A study of Mus musculus with 4 samples.

How the data were processed

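Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 4 libraries of B16-F10 cells, a mouse melanoma cell line. Per the labels, 2 libraries are wild type and 2 come from cells whose Ssbp4 gene was knocked out with CRISPR-Cas9, and the protocol names a guide against an intergenic site of chromosome 2 as the control. The labels number the libraries of each genotype but do not say that they came from separate cultures, so differences between replicates may be technical.

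The deposited files are peak lists in narrowPeak format, 1 per library, so the calls were made in each library and not on pooled reads. Peaks were called with MACS2 and positions refer to the GRCm39 build, per the submitters' processing notes. The aligner, the versions, any filter on duplicate reads and any shift of the reads for the Tn5 insertion site are not given in the sources used here. Each call carries a display score, deposited by the authors and not used in any comparison. The fold enrichment of each summit, as deposited by the authors, is the ratio of the reads piled up at the summit to the local background. The authors also deposited the −log10 p-value and the −log10 q-value of each call. The lowest −log10 q-values were 1.31, 1.33, 1.31 and 1.30 in wild-type replicates 1 and 2 and knockout replicates 1 and 2, so every list reaches down to a q of about 0.05. These values belong to each peak and depend on the depth of the library, and the comparison of lost and gained regions used them only to describe, rank or filter calls within a list. Analyses added after the data were seen also set ranks by the p-value side by side over the regions called in all 4 libraries, and compared pileups recovered from the fold and the p-value between genotypes, relative to the rest of the genome.

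Positions were converted to 1-based coordinates. Calls on chromosomes 1 to 19, X and Y were kept (no calls of a library overlapped each other), and the calls of the 4 libraries were merged into union regions where they overlapped by at least 1 bp. A region was called lost when both wild-type libraries and neither knockout library had a call in it, and gained when the reverse held. Strong regions were those in which both libraries had a call above the 50th percentile of their own list by the −log10 p-value. Because 4 libraries can be split into 2 and 2 in only 3 ways, no permutation p can go below 0.33, and no test across libraries was made. The same counts were taken in the other 2 splits, which pair a wild-type with a knockout library, as the level that differences between replicates reach. Whatever both libraries of a genotype share, such as a lower fold enrichment or the cell population that was edited, does not enter the counts of these splits. List length also differed within each genotype. Replicate 2 had the longer list in both genotypes, so list length does enter the split by replicate number. For each of 21 chromosomes, lost and gained regions on that chromosome and elsewhere were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Regions are not replicates and neighbouring regions are not independent, so these p-values describe the 4 libraries. Shares of calls are given with Wilson 95% intervals, which cover counting error only.

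The rule for named items, fixed before the data were examined, took the 12 strong lost and the 12 strong gained regions with the highest rank, the rank being the lower of the percentiles in the libraries that have the call. It also asked for the genes next to these regions, for Ssbp4 itself and for the members of fixed gene lists. The gene table at hand belongs to another build of the mouse genome than the peak lists, and no positions were converted between builds. Genes, promoters, gene lists and sequence motifs were therefore not analysed here, and regions are named by position alone.

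Total read numbers per library were not used here. The pileup at the genome-wide background, which rises with read number and with the extended read length, was recovered from the lists, since the deposited fold is (pileup + 1) divided by (background + 1) and the p-value is the Poisson tail of the same numbers. This gave a pileup within 0.05 of a whole number for 99.99%, 100.0%, 99.99% and 99.99% of the calls in wild-type replicates 1 and 2 and knockout replicates 1 and 2. Ratios of recovered pileups are given with the standard error of the median from 1000 bootstrap draws of regions.

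The alternatives were a stricter q-value (−log10 q of at least 5), lists of equal length, a call covering at least 50% of the region, windows of 501 bp around summits, every sequence but the mitochondrial genome, strong calls above the 75th percentile, and leaving out each library in turn. On simulated lists of 44000 regions for the wild type against knockout comparison, 200 of 200 lost and 200 of 200 gained regions were recovered. These regions were removed from both libraries of a genotype and every other region was kept in all lists. The recovery therefore checks the code only, and not how weak calls near the calling threshold behave. With gained regions loaded on chromosome 6 in 100 further draws, the chromosome test passed chromosome 6 in 100 and another chromosome, which the loading depletes, in 44. With chromosome 6 left out of the test, another chromosome passed in 1. The recovery of pileups, tested on 3000 simulated summits, returned 100% of them to within 0.5 reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.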

Results

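The data are 4 lists of accessible regions in B16-F10 melanoma cells, 2 from wild-type cells and 2 from cells without Ssbp4, a gene of the single-stranded DNA-binding protein family whose products act with the LIM-domain-binding transcription cofactors. The series concerns immune evasion by tumour cells that express SSBP4 and the synthesis of cholesterol, and the comparison asks which accessible regions differ when the gene is knocked out. Ssbp4 lies on chromosome 8, and calls over the gene itself were not analysed here because the positions of genes in this build were not used. The knockout label of each library was therefore not checked from the lists.

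On chromosomes 1 to 19, X and Y, the wild-type libraries had 59215 and 63080 calls and the knockout libraries 50068 and 57698. The calls covered 56.9 and 57.7 Mb in wild type and 51.5 and 54.0 Mb in the knockout, with median lengths of 890, 838, 959 and 863 bp. The median fold enrichment at the summits was 5.87 and 6.20 in the wild-type libraries and 4.58 and 4.73 in the knockout libraries, as deposited by the authors. The background pileup recovered from the lists, which rises with the number of reads and with their extended length, was 14.7 and 15.1 in wild type and 17.2 and 17.4 in the knockout. Per 1000 bp of the shortest call of each list, a measure nearer to read number, it was 43.6 and 49.3 in wild type and 45.2 and 51.6 in the knockout, so the genotypes overlapped. The knockout libraries thus had a lower fold enrichment, with shorter lists.

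The covered base pairs of the wild-type libraries overlapped with a Jaccard index of 0.805, the highest of the 6 pairs. The knockout libraries shared 0.739, and the 4 pairs that cross genotype lay between 0.690 and 0.739. The knockout pair exceeded the closest crossed pair, wild-type replicate 1 with knockout replicate 2, only in the digits beyond those printed. By shared base pairs, the knockout replicates were thus no nearer to each other than that crossed pair by any margin that could be told from the spread.

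Of 72251 union regions, 44000 (60.9%) were called in all 4 libraries. Loss of Ssbp4 went with 5122 lost regions (7.09% of the union) and 1096 gained regions (1.52%), a ratio of 4.67. In the other splits of the same libraries, the 2-and-2 pattern held in 235 and 1328 regions and in 616 and 396 regions. The count of lost regions thus exceeded every count in the other splits, and the count of gained regions did not exceed the 1328 shared by the replicates 2 alone. Replicate 2 had the longer list in both genotypes, and with equal lists that count was 516 against 2105 gained regions. The comparison for gained regions thus depends on the list lengths. Lost regions were short, with a median of 543 bp against 752 bp for gained regions and 1178 bp for regions called in all 4 libraries. They were also weak calls: 92.4% of lost and 99.5% of gained regions lay below the median of both lists that held them.

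The ratio depended on how the lists were cut. With the strongest 50068 calls of each library, 2817 regions were lost and 2105 gained, a ratio of 1.34, and the highest count in the other splits was 516. Lists of equal length push the lost and gained counts towards balance by construction, so this ratio does not show that list length was the cause. Under a −log10 q of at least 5, the gained regions numbered 557 and the ratio was 9.62. Leaving out a library loosens the definition and raised the counts. Without wild-type replicate 1 there were 9978 lost and 1665 gained regions, without wild-type replicate 2 there were 1869 gained, without knockout replicate 2 there were 10091 lost and 2829 gained, and without knockout replicate 1, the shortest list, there were 4670 gained and the ratio was 1.32.

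**Figure D1:**
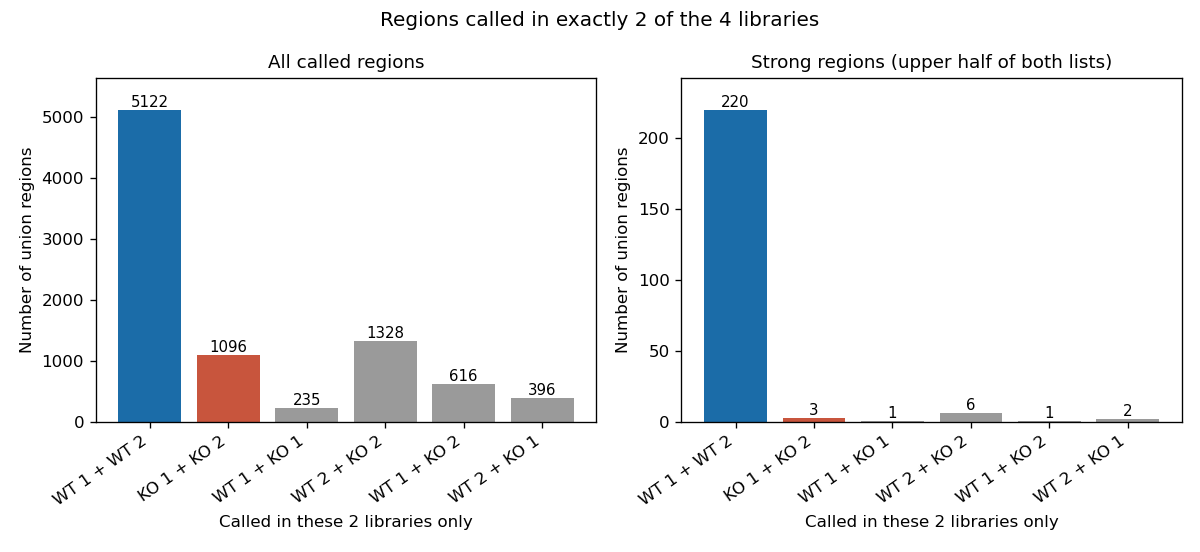
Number of union regions called in exactly 2 of the 4 libraries, for each possible pair of libraries (WT, wild type; KO, Ssbp4 knockout), over all calls on the left and over calls above the median of both lists on the right. The wild-type pair holds 5122 regions and 220 strong regions, above every other pair in both plots.

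Among strong calls, the regions missing in the knockout far outnumbered those gained. There were 220 strong lost regions, 0.759% of the 28971 strong regions of the wild-type libraries, and 3 strong gained regions, 0.0122% of the 24690 strong regions of the knockout libraries. The other splits gave 1, 6, 1 and 2. The strong lost regions lay on 20 chromosomes, with 22 on chromosome 2 and 21 on chromosome 1, and had a median length of 588 bp and median folds of 7.99 and 8.98 in the wild-type replicates. With equal lists all 220 were still lost, which that setting cannot undo, and 71 of them were still strong by the medians of the shorter lists, against 2 gained and at most 2 in the other splits; with fixed-width windows around summits 434 strong regions were lost and 155 gained. Without wild-type replicate 1 the strong lost regions numbered 433 and without knockout replicate 2 they numbered 647, and above the 75th percentile only 1 was lost and 0 gained.

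The highest-ranked strong lost region lay on chromosome 18 at 85716060–85716416, with a fold enrichment of 22.2 in wild-type replicate 1 and 26.4 in replicate 2, and it was the only lost region above the 75th percentile of both lists. At 357 bp it was close to the shortest call of either wild-type list, 337 and 307 bp, and shorter than any call of knockout replicate 1, whose shortest was 380 bp (338 bp in replicate 2). In all, 15 of the 220 strong lost regions (6.82%) were shorter than the shortest call of knockout replicate 1 and 0 shorter than that of replicate 2. On chromosome 1, the region 164180939–164181406 had a fold of 15.1 in replicate 1 and lay at the 75.3 and 74.9 percentiles, and 89382188–89382705 had folds of 6.06 and 7.29. On chromosome 8, which carries Ssbp4, the region 84483067–84483614 had folds of 11.8 and 12.7. The region 129043155–129043836 of chromosome 4 had folds of 13.4 and 14.5, and 107745424–107745983 of chromosome 10 had 12.6 and 15.8. On chromosome 2, the regions 103271787–103272559 (folds 8.74 and 8.93) and 138972589–138973432 (13.6 and 13.8) were lost. Chromosome 11 held 3 of the 12, at 60188741–60189218 (3.46 and 3.89), 52456309–52456709 (4.62 and 4.96) and 34720337–34720764 (6.96 and 7.20), and chromosome 17 held the last, at 6792025–6792764 (5.28 and 5.69). All 12 were still lost where a call had to cover 50% of the region and in fixed-width windows around summits, the alternatives that could have removed them.

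**Figure D2:**
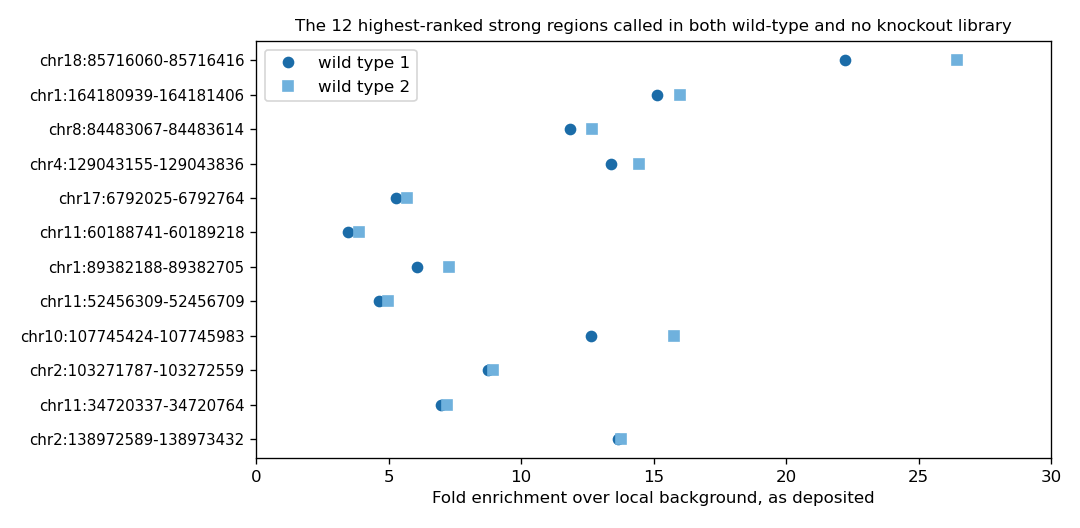
Fold enrichment over local background, as deposited by the authors, of the 12 highest-ranked strong regions called in both wild-type libraries and in no knockout library, by GRCm39 position; circles are wild-type replicate 1 and squares wild-type replicate 2. Replicate 2 has the higher fold in each of the 12 regions, and the region on chromosome 18 reaches 22.2 and 26.4.

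The only strong gained regions were 24759108–24759771 on chromosome 17, with folds of 4.59 and 4.79 in knockout replicates 1 and 2, 111844536–111844953 on chromosome 12, with 2.70 and 3.07, and 39593786–39594518 on chromosome 18, with 5.56 and 6.07. These ranked between the 50.9th and the 58.4th percentile of their lists, and all 3 were still gained where a call had to cover 50% of the region and in fixed-width windows. Their number was within the range of the other splits. Strong gained regions numbered 23 where a call had to cover 50% of the region and 155 in fixed-width windows, settings for which the other splits were not set beside them. Without wild-type replicate 1 or 2 the strong gained regions numbered 5 and 8, and without knockout replicate 1 or 2 they numbered 19 and 8.

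Gained regions were concentrated on chromosome 6. It held 196 of the 1096 gained regions (17.9%) against 258 of the 5122 lost regions (5.04%) and 7.28% of the regions called in all 4 libraries (odds ratio 4.11, adjusted p = 9.2e-39, Fisher's exact test over regions). The share of all calls that lay on chromosome 6 was 7.25% (95% interval 7.04–7.46) and 7.18% (6.98–7.38) in wild type and 8.14% (7.91–8.39) and 8.55% (8.32–8.78) in the knockout, so the intervals of the genotypes did not overlap. Chromosome 6 also held 11.5% and 9.79% of the regions in the split by replicate number and 13.0% and 10.4% in the crossed split, so regions called in only 1 library of each genotype were frequent there. Against these regions together (10.8%), gained regions were still more frequent on chromosome 6 (odds ratio 1.80, adjusted p = 1.4e-08, Fisher's exact test) and lost regions less frequent (odds ratio 0.438, adjusted p = 2.1e-19, Fisher's exact test), a comparison added after the data were seen. The knockout libraries had 1.02 times as many calls on chromosome 6 as the wild-type libraries, against 0.870 times on the other chromosomes. The odds ratio was past the threshold in all 8 alternatives, at 2.11 with equal lists and 2.45 with the stricter q-value.

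In all, 13 of 21 chromosomes differed between lost and gained regions at an adjusted p under 0.05, and 0 did in each of the other splits, which hold fewer regions. With lost and gained regions drawn down to the sizes of those splits 100 times, the median number of chromosomes past the threshold was 2 (range 1 to 6) and 4 (range 1 to 11), and chromosome 6 passed in 100 of 100 draws at both sizes. The excess on chromosome 6 lowers the share of gained regions elsewhere, and with chromosome 6 left out 11 of the other 20 chromosomes differed, and only chromosome 9 dropped out. In the test over all chromosomes, gained regions were more frequent on chromosomes 6, 11, 12, 14 and 15, and lost regions on chromosomes 2, 3, 4, 9, 13, 16, 19 and X. The test sets lost against gained regions only. Against the regions called in all 4 libraries, lost regions were not more frequent on chromosome 4 (5.84% against 6.26%). Gained regions were not more frequent on chromosome 11 (7.57% against 8.08%), while the other chromosomes listed kept their direction. Among the chromosomes past the threshold, chromosome 19 stood furthest from chromosome 6, with 198 lost and 9 gained regions (odds ratio 0.206, adjusted p = 8.3e-08, Fisher's exact test). Chromosome 8, with 253 lost and 56 gained regions, did not pass the threshold (odds ratio 1.04, adjusted p = 0.859, Fisher's exact test). With the stricter q-value 6 chromosomes differed.

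**Figure D3:**
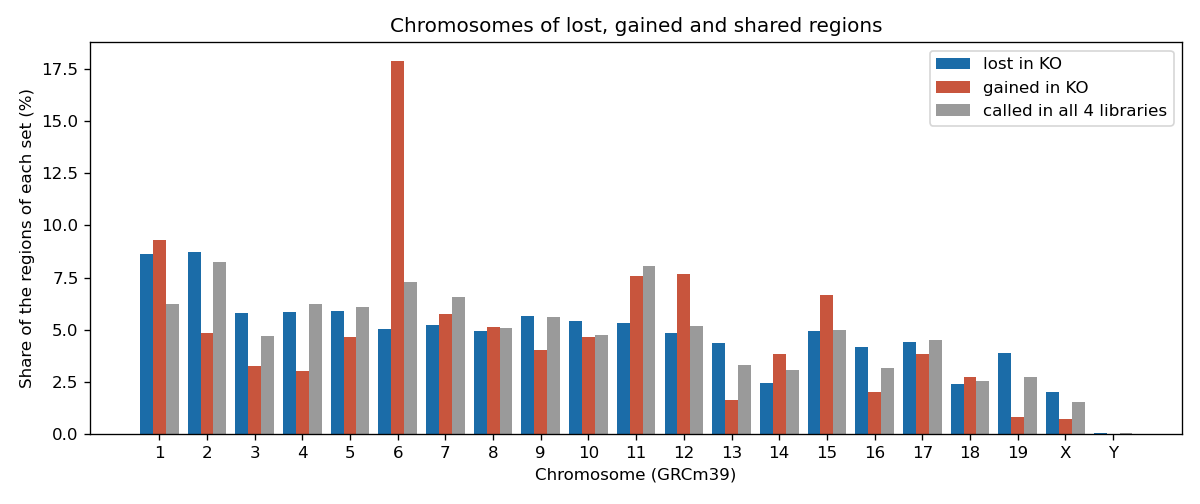
Share of the lost, the gained and the shared regions that lies on each chromosome, in percent of each set; bars are regions lost in the knockout, gained in the knockout and called in all 4 libraries. Chromosome 6 holds 17.9% of the gained regions, 5.04% of the lost and 7.28% of the shared regions.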

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

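The tests of depth, of the ranks of the lost calls, of clusters on chromosomes 6, 14, 18 and X, of chromosomes 14, 18 and X taken singly, and of the unlocalised and unplaced sequences, and the spread between chromosomes as the yardstick for copy number, were chosen after the result was seen. The comparisons above leave out calls on unplaced and unlocalised sequences, and these calls were more numerous in both knockout libraries, 137 and 148, than in the wild-type libraries, 126 and 117, although the knockout lists were shorter. The sequence GL456210.1 had 8 and 7 calls in the knockout and 3 and 3 in wild type. GL456211.1 had 16 and 18 against 9 and 9, and GL456221.1 had 13 and 16 against 10 and 7. Both knockout libraries lay above both wild-type libraries on 5 of 23 sequences and below on 2. Chance gives at most 1 in 6 for either, and less where counts tie, as many of these small counts did. On 4 sequences the knockout libraries led by a gap of 2 or more calls. Outside these 4 the totals were 93 and 86 in wild type and 85 and 93 in the knockout. The 4 were picked for that gap, so a balance elsewhere was likely and does not show that the rise was confined to them.

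Gained regions were also dense on chromosome 8 between 20 and 22 Mb, where 22 were gained and 1 lost (12 gained with the stricter q-value, 37 with equal lists and 39 without knockout replicate 1), and where the summit pileups of the 47 regions called in all 4 libraries exceeded the rest of chromosome 8 by 0.89 in the median log2 ratio of knockout to wild type. More copies of the segment, or more reads mapped to it, would give this excess, while reads shared with the unlocalised sequences cannot be told apart, since the lowest knockout total there lay 11 calls above the highest of wild type but no sequence comparison ties them to chromosome 8. The rise in pileup was not limited to the segment, since the 90 regions called in all 4 libraries on 20 unplaced or unlocalised sequences stood 0.73 above the standard chromosomes in the same log2 ratio (SE 0.06). A higher share of background reads in the knockout libraries, which pile up on sequence present in many copies, may therefore contribute to the gained calls of the segment. A gain of copies in the knockout cells remains open, and a biological opening of the segment is untested.

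More regions were lost than gained. The background pileup per 1000 bp of the shortest call gave no sign of lower depth in the knockout, at 45.2 and 51.6 against 43.6 and 49.3 in wild type. Knockout replicate 2, with the highest value, had fewer calls (57698) than wild-type replicate 1 (59215), with the lowest. The genotypes overlapped (lowest knockout minus highest wild type −4.13) and read totals were not used, so lower depth is not excluded. The ratio was 1.34 with equal lists. Such lists push the lost and gained counts towards balance by construction, so this does not decide whether list length was the cause. Lower fold enrichment over background is left open as a cause of the weak losses. Over the 44000 regions called in all 4 libraries, the median fold was 7.45 and 8.28 in wild type and 5.12 and 6.01 in the knockout. Enrichment was thus lower in both knockout libraries at the same regions. Of lost regions, 92.4% lay below the median of both wild-type lists. So did 99.5% of gained regions in the knockout lists, so the share of weak calls does not separate them. With equal lists 71 regions were strong and lost, against at most 2 in the other splits. A lowering of enrichment that keeps the order of the regions does not explain these 71. Whether the lowering kept that order was not tested, so lower enrichment is not excluded for them. The other 149 strong lost regions were not decided by this test. An effect of Ssbp4 is untested and stays a hypothesis beside these technical explanations.

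For chromosome 6, where gained regions were concentrated, the median log2 ratio of pileups exceeded that of the other chromosomes by 0.082. The 16 chromosomes other than 6, 14, 18, X and Y ranged from −0.088 to 0.030 (SD 0.034), so a higher copy number cannot be told apart from other causes. Relative to the genome-wide level, the local background on chromosome 6 was 1.20 and 1.12 in wild type and 1.45 and 1.37 in the knockout. It was thus raised in both genotypes, and chromosome 11 had similar values (1.22 and 1.14, 1.42 and 1.34). The cause of this was not tested. The 2 fullest 10-Mb bins held 29.1% of the gained regions of chromosome 6, so 2 such bins did not hold most of them. A larger number of clusters is not excluded, since only the 2 fullest bins were counted. Regions of chromosomes 14, 18 and X, among the 44000 called in all 4 libraries, rose in rank by medians of 2.45, 1.89 and 1.79 percentile points in the knockout. Chromosome 6 rose by 0.431 and the median 10-Mb bin of the other chromosomes by 0.355. The rise was spread along the 3 chromosomes, as 97.0% of their 33 bins with at least 20 regions lay above that median bin. They were picked for their rise in the same ranks, so most bins were likely to lie above it and no chance level applies. The excess in pileup was 0.121 on chromosome 14, in the direction that a higher copy number in the knockout cells would give. On chromosome 18 it was 0.084, where copy number cannot be told apart from the spread between chromosomes. Chromosome X, at 0.022 (SE 0.009), lay under the bound of 0.05 set beforehand to exclude copy number for the 3 together, but that bound left out the spread between chromosomes, whose SD of 0.034 is larger than the distance to it, so copy number stays open there too. For chromosomes 6, 14, 18 and X, the excess that an extra copy in every cell would give was not set beside these values. Whether they are large enough for such a gain was therefore not tested. A change in these chromosomes caused by the loss of Ssbp4 was not separated from differences between the cell populations that were edited.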

How the results depend on the processing

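All alternatives for the ratio of lost to gained regions, the chromosomes, chromosome 6, the 1-Mb windows and the chromosome 8 segment were chosen after seeing the data, and the rest before the data were examined. With lists of equal length there were 2817 lost and 2105 gained regions (ratio 1.34) and 71 strong lost regions. With a −log10 q of at least 5 there were 557 gained regions, a ratio of 9.62, 1 strong gained region and 6 chromosomes past the threshold. Strong gained regions numbered 23 where a call had to cover 50% of the region, and fixed-width windows around summits gave 434 strong lost and 155 strong gained regions. Above the 75th percentile, 1 strong region was lost and 0 were gained. Leaving out each library in turn gave 6153 to 10091 lost and 1665 to 4670 gained regions, ratios of 1.32 to 5.99, 248 to 647 strong lost and 5 to 19 strong gained regions. These counts rise by construction, because fewer libraries have to share the pattern; the causes of the other changes were not tested. With every sequence but the mitochondrial genome, 5125 regions were lost and 1112 gained. The odds ratio on chromosome 6 stayed past the threshold under all 8 alternatives, between 2.11 and 4.16. The number of 1-Mb windows dense in lost or gained regions was 2, both in the chromosome 8 segment, and moved by over 1.5 times in all 8 alternatives of that window size: 1 with the stricter q-value, 6 with equal lists, 9 with 50% cover, 1 with fixed-width windows around summits and 5 to 59 leaving out each library, 59 without knockout replicate 1. With windows of 2 Mb it was 3.

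The replicate numbers shared by the genotypes gave a correlation of deviations of 0.107 over 44000 regions, from only 2 pairs of libraries, so the libraries share a number and are not taken as paired. The replicate block, which asks for loss within both numbers, selects 5122 lost and 1096 gained regions by construction, as does the crossed pairing. Alternatives for promoters, gene lists, motifs and named genes were not run, since no gene positions of this build were used. Read totals were not used here, so a region without a call is one not detected at the depth of that list.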

Other observations

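The analyses of ranks and of recovered pileups in this part were chosen after the data were seen. Among the 44000 regions called in all 4 libraries, which give lists of equal length, many changed in rank without losing their call. Between the genotypes, 1884 regions ranked over 10 percentile points higher in both wild-type libraries than in both knockout libraries and 1059 ranked over 10 points higher in the knockout, against 24, 27, 12 and 16 in the other splits. Gaps over 20 points occurred in 297 and 90 regions, and in 0 regions in the other splits. The widest fall in the knockout was on chromosome 6 at 113219772–113220480, which ranked at the 71.2 and 66.9 percentiles in wild type and at 15.9 and 14.8 in the knockout. It was followed by 153852759–153853651 on chromosome 4, at 61.9 and 53.1 against 3.95 and 6.80, and by 87212511–87213576 on chromosome 3, at 78.4 and 75.3 against 19.8 and 31.5. The widest rise was on chromosome 17 at 13874876–13875344, from 12.8 and 10.6 to 61.2 and 54.0, followed by 18223964–18224961 on chromosome 2, from 9.40 and 13.0 to 51.6 and 55.3, and by 37392064–37392700 on chromosome 6, from 4.37 and 12.3 to 49.7 and 50.3. Across these regions, which are not independent replicates, Spearman's rho of the ranks was 0.988 for the wild-type pair and 0.981 for the knockout pair, against 0.954 to 0.964 for the 4 crossed pairs. By rank, the replicates of each genotype were thus nearer to each other than to any library of the other genotype.

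Recovered pileups were also compared in 1508 windows of 1 Mb that held at least 8 regions called in all 4 libraries, relative to the median of the standard chromosomes. The lowest window in the knockout was on chromosome 15 between 90 and 91 Mb, where the median log2 ratio was −0.68 (SE 0.11), 14 of 17 regions lay below 0, 3 regions were lost and 0 gained. A window nearby on the same chromosome, from 92 to 93 Mb, had −0.49 (SE 0.13) over 8 regions. The highest was on chromosome 7 between 59 and 60 Mb, at 1.10 (SE 0.03), with 12 of 12 regions above 0. Chromosome 5 between 15 and 16 Mb lay between the windows of the chromosome 8 segment, at 0.87 (SE 0.04), with 59 of 60 regions above 0. Medians exceeded 0.5 in 7 windows and fell below −0.5 in 1 between the genotypes, and did so in 0 windows in the other splits, whose medians lay between −0.36 and 0.20. No test of an explanation was made for these windows.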
